A study of Mus musculus with 28 samples.

How the data were processed

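The 28 libraries were bulk RNA-seq of 4 sorted bone marrow populations in 2 genotypes. Per the labels' protocols, RNA was extracted with a column kit and libraries followed standard Illumina steps. Per the submitters' processing notes, HISAT2 2.2.1, SAMtools 1.9, Subread's featureCounts and DESeq2 were used with GRCm38 (mm10). The annotation and the strand setting were not given in the sources used here, so antisense and overlapping genes cannot be told apart by strand.

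Each population had a gene table of its own, and tests stayed within a table. The values deposited for HSPC, prepro-B and CD11b+ cells were a signal, gene counts that the authors had divided by a size factor per library. Dividing each column by the value of 1 read gave whole numbers for 100% of values within 0.001, so whole reads were recovered. The table deposited for pre-B cells held raw counts of whole reads, although its name spoke of normalised values, so the planned test for normalised values was replaced by the count test that the plan named for this case. The authors' tables listed 17661 genes for HSPC, 18558 for prepro-B, 35976 for pre-B and 16604 for CD11b+ cells. Every gene listed had at least 9 reads in total in the HSPC and prepro-B tables and at least 5 in the CD11b+ table, while 11490 genes of the pre-B table had 0 reads. Symbols were matched to the GRCm38.p6 gene table for positions: 16242, 17061, 32501 and 15274 matched directly and 602, 621, 1005 and 569 by a unique synonym, in the order above. The gene of the selenocysteine tRNA was not analysed here.

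Genes with a mean value of at least 10 were tested. HSPC, prepro-B and CD11b+ cells were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1) with an intensity trend, so fold changes are on that scale and understate the change of low genes. Pre-B counts were tested with edgeR 4.0.16 (quasi-likelihood, TMM). All tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05, and compared Trsp KO with control libraries of the population without further terms. The median residual SD was 0.15, 0.30, 0.38 and 0.24 on the log2 scale in HSPC, prepro-B, pre-B and CD11b+ cells. Replicate numbers were not taken as pairs, because correlations of same-numbered libraries did not show pairing, which so few libraries cannot exclude. The 2 sets of library numbers taken within HSPC, prepro-B and pre-B cells each held 2 libraries of each genotype.

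There were 32 gene lists, fixed before the data were examined: selenoproteins, selenocysteine machinery, NRF2 targets, ferroptosis, cholesterol synthesis, p53 targets, ATF4 targets, endoplasmic reticulum chaperones, interferon-stimulated genes, NF-kB genes, DNA replication, mitosis, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, long-term stem cell genes and genes higher in aged stem cells. The others were lymphoid priming, B-cell lineage, late B maturation, neutrophil, monocyte, plasmacytoid dendritic cell, NK, T-cell, plasma-cell, basophil with mast cell and eosinophil, erythroid, megakaryocyte, stromal, handling stress and sex-linked genes. Some genes stand in more than 1 list. Lists with at least 5 tested genes were tested with limma's camera (correlation preset at 0.01), adjusted over the lists of a comparison, and alternatives were camera with an estimated correlation and the rotation test fry. Of the sex-linked genes, Xist was read in all libraries, and the list was too short to test. The Y-linked genes had at most 2 reads in any pre-B library and had no entry in the other tables. Named genes were, per comparison, the 8 rising and 8 falling called genes with the largest change, a mean of at least 50 and no overlap between groups, leaving out gene models and pseudogenes (125 of them in HSPC), all selenoproteins, and up to 4 genes with the smallest p per list.

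The procedure was tested on simulated data, counts drawn from the real means, dispersions and library sizes, with 200 genes changed by a known fold. In HSPC 13216 genes were run, and 56%, 75.5%, 100% and 100% of genes changed 1.5-, 2-, 4- and 8-fold were recovered, with 11 unchanged genes among 188 called. In prepro-B cells (13831 genes) the shares were 16.7%, 55.1%, 87.5% and 89.6%, with 7 unchanged of 129. In pre-B cells (13462 genes) they were 4%, 36.2%, 73.5% and 79.6%, with 3 of 99. In CD11b+ cells (12548 genes) they were 20.4%, 40%, 89.6% and 85.1%, with 4 of 118. Of 20 unshifted lists 0, 0, 0 and 1 were called. Genes were drawn independently, so this does not cover correlation between the genes of a real list.

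Alternatives covered the pseudocount, the filter, each library left out, a replicate block, rescaling, quantile normalization, robust variance, library weights, a library-number term, and edgeR and DESeq2 1.42.0 on whole reads. Alternatives chosen after seeing the data were fits without Trsp KO 3 and 4, limma on the pre-B counts, fits without the globin genes and the models of differences between populations. Positions are 1-based. The test for granulocyte RNA in pre-B cells took genes by their control and CD11b+ values and a predicted mean of at least 10, with 0.5 CPM added before logarithms, and 8 of its genes that missed the filter counted as not passing. Its genes, and the erythroid markers used for HSPC, were settled after earlier versions of these tests had been seen.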

Results

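RNA was sequenced from sorted bone marrow cells of mice treated to delete Trsp and of control mice. Trsp encodes the tRNA that inserts selenocysteine, the amino acid that defines selenoproteins. The comparison thus addressed how stem, lymphoid and myeloid cells differ in mice treated to delete it. Whether the changes arose within the sorted cells or elsewhere in the mouse was not tested. Trsp KO mice carried floxed Trsp alleles and Mx1-Cre, a recombinase gene switched on by interferon. Control mice carried the floxed alleles without Cre, so effects of Cre itself were not separated from those of the deletion. All mice were C57BL/6 and received pI-pC, a double-stranded RNA analogue that induces interferon, as 3 doses of 500 µg on alternate days at 7 weeks of age. Marrow from femora and tibiae was taken 9 weeks after the last dose.

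The cells were sorted into 4 populations. HSPC were lineage-negative, cKit-positive stem and progenitor cells. Prepro-B cells, the earliest B-lineage stage, lacked CD19 and carried CD43, while pre-B cells carried CD19 and lacked CD43, and both gates excluded cells with T-cell, myeloid, erythroid or IgM markers. CD11b+ cells were myeloid. There were 4 control and 4 Trsp KO libraries of HSPC, of prepro-B and of pre-B cells, and 2 of each genotype for CD11b+ cells, 28 in all. Reads assigned to genes ranged from 18.5 to 21.8 M per HSPC library, 15.5 to 21.4 M per prepro-B library, 14.7 to 20.7 M per pre-B library and 19.3 to 28.8 M per CD11b+ library. Whether each library came from a separate mouse was not given in the sources used here, so p-values measure the spread between these libraries. Intervals and floors cover counting error only.

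The targeted tRNA gene was not analysed here, because 0 entries of the gene tables carried its name, and the selenoprotein mRNAs served as the nearest readout. The mRNA of Gpx1, a cytosolic glutathione peroxidase (chromosome 9, 108339080 to 108340342, GRCm38), fell in HSPC from a normalised read count of 19769 ± 582 (SD, n = 4) to 3709 ± 178. In prepro-B cells it fell from 44267 ± 4753 to 8368 ± 313, and in CD11b+ cells from 57438 ± 8254 to 10760 ± 526 (n = 2). Sepw1, which encodes selenoprotein W (chromosome 7, 15917208 to 15922371), fell in all 4 populations, with log2 fold changes of -3.05 ± 0.10 (SE) in HSPC, -2.42 ± 0.14 in prepro-B, -2.42 ± 0.24 in pre-B and -2.57 ± 0.31 in CD11b+ cells. The gene of selenoprotein H, listed as 2700094K13Rik (chromosome 2, 84669215 to 84670708), fell by 2.79, 2.67, 2.47 and 2.78 on the log2 scale in the same order. Sepp1, the gene of the selenium transporter selenoprotein P (chromosome 15, 3270767 to 3280510), fell by 1.30, 1.61, 1.32 and 1.46.

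Not every selenoprotein mRNA moved this way. Of 20 selenoprotein genes tested in HSPC, 12 fell, 2 rose and 6 did not pass the test, and adjusted over the list alone 12 fell and 4 rose. The falling genes included Gpx4, the phospholipid hydroperoxide peroxidase (log2 -1.16), and Selt (log2 -1.03), whereas Dio2 (log2 0.49) and Sephs2, the selenophosphate synthetase gene (log2 0.38), rose. In prepro-B cells 6 fell and 2 rose (adjusted over the list alone, 10 and 3), and the risers were again Dio2 and Sephs2. In CD11b+ cells 6 fell and 0 rose by limma (adjusted over the list alone, 11 and 0), Gpx3, the secreted glutathione peroxidase, among them at log2 -2.68. In pre-B cells 4 fell and 1 rose (adjusted over the list alone, 5 and 3): Txnrd1, a thioredoxin reductase, was higher at log2 1.24, and Gpx1, at log2 -1.27, did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0595).

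As a list, the selenoprotein genes fell in HSPC (median log2 -0.50, limma camera, Benjamini-Hochberg adjusted p = 5.41e-06; adjusted p = 0.0743 with an estimated correlation). They fell in prepro-B cells (median log2 -0.49, adjusted p = 4.98e-10; adjusted p = 0.0243 with an estimated correlation). They also fell in CD11b+ cells (median log2 -0.47, adjusted p = 4.63e-14; adjusted p = 0.303 with an estimated correlation). In pre-B cells the median was log2 0.16, opposite in sign to the direction of camera's test, which did not pass (adjusted p = 0.5). Within HSPC, prepro-B and pre-B cells the 4 lower- and the 4 higher-numbered libraries were taken as sets, which the labels do not name. Within the lower- and higher-numbered sets the medians were -0.45 and -0.50 in HSPC, -0.61 and -0.37 in prepro-B and 0.01 and 0.15 in pre-B cells.

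**Figure D1:**
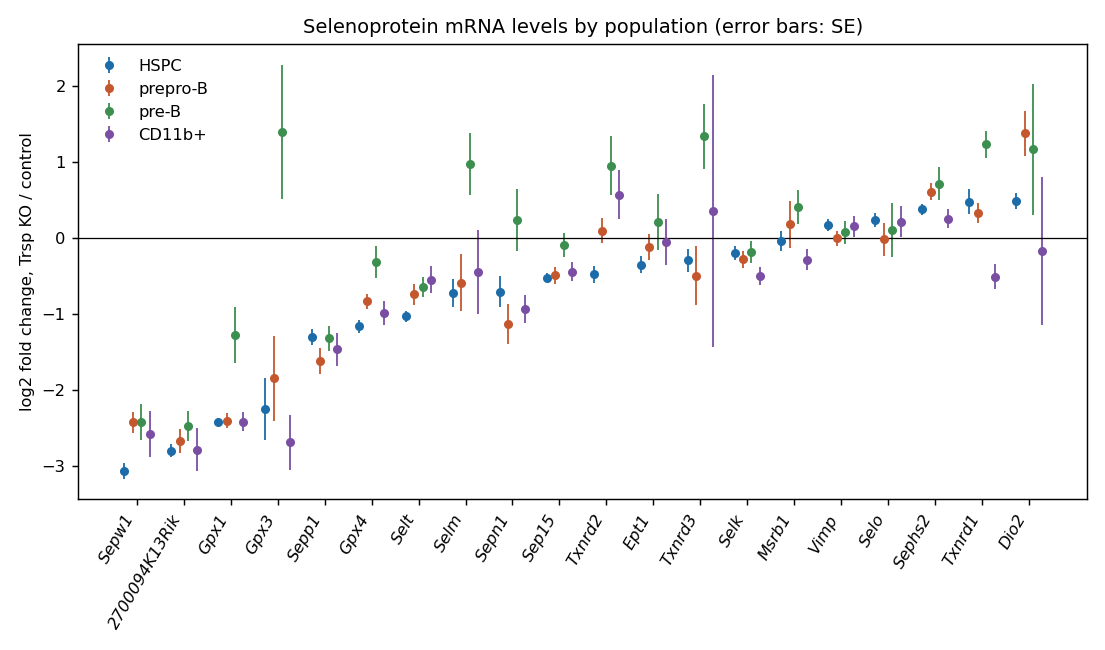
Log2 fold changes of 20 selenoprotein mRNAs (vertical axis, Trsp KO over control; points are fitted changes, bars are SE) in 4 populations, with genes ordered along the horizontal axis. Sepw1 and 2700094K13Rik lie between -3.05 and -2.42 in each population, while Gpx1 is at -1.27 in pre-B cells and near -2.41 in HSPC.

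In HSPC the largest rises among the genes that the fixed rule names were in NRF2 antioxidant targets. Slc7a11, the cystine transporter (chromosome 3, 50364936 to 50499087), rose from a normalised read count of 14.9 ± 3.4 (SD, n = 4) to 1016 ± 265, a log2 change of 5.99 ± 0.20 (SE). Nqo1, a quinone reductase (chromosome 8, 107388225 to 107403205), rose from 334 ± 44 to 3060 ± 363. Of 36 NRF2 targets tested, 29 rose, Lhpp fell and 6 did not pass, with a list median of log2 0.92 (within the library-number sets 0.74 and 0.98; camera adjusted p = 2.55e-22). That call was lost with an estimated correlation (adjusted p = 0.0518 with an estimated correlation). The 8 largest rises by the fixed rule were Slc7a11, the glutathione transferase Gsta3 (log2 5.95), Osgin1 (4.69), the malic enzyme Me1 (4.39), Cbr3 (4.03), Pir (4.03), the sulfiredoxin Srxn1 (3.60) and Nqo1 (3.19). The 8 largest falls were Trim2 (log2 -3.13), Sepw1, the stearoyl-CoA desaturase Scd1 (-2.98), the amino acid transporter Slc6a20a (-2.95), Spon2 (-2.59), the glutaminase Gls2 (-2.42), Gpx1 and Gpx3 (-2.24).

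Genes of proliferation and respiration fell by small amounts in HSPC. Of 30 DNA replication genes 21 fell and 0 rose by limma, among them the helicase subunit Mcm7 (log2 -0.68) and the cyclin Ccne1 (-0.75), and the list median was -0.27 (within sets -0.17 and -0.35; camera adjusted p = 7.18e-11, adjusted p = 0.463 with an estimated correlation). Of 30 mitosis genes 20 fell, with Mki67 at log2 -0.50 and Plk1 at -0.37, and a median of -0.22 (within sets -0.17 and -0.26; camera adjusted p = 1.77e-10, adjusted p = 0.412 with an estimated correlation). Of 35 nuclear genes of oxidative phosphorylation 20 fell, with Ndufs1 at log2 -0.41 and a median of -0.19 (within sets -0.13 and -0.27; camera adjusted p = 2.84e-09, adjusted p = 0.463 with an estimated correlation). Glycolysis genes moved up: 8 of 18 rose, including Aldoa (log2 0.56) and Pkm (0.77), and Pfkm fell (median 0.22, within sets 0.21 and 0.26; camera adjusted p = 0.00706, adjusted p = 0.463 with an estimated correlation).

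Some stem-cell, lymphoid and monocyte genes rose in HSPC, and 13 erythroid markers fell. Of 25 long-term stem cell genes 12 rose, including Meis1 (log2 0.57) and Ly6a, which encodes Sca-1 (1.34), with a median of 0.51 (within sets 0.42 and 0.53). Of 21 genes known to be higher in aged stem cells 8 rose, with the adhesion receptor Selp at log2 1.51 and a median of 0.49 (within sets 0.30 and 0.50). Camera adjusted p-values for these lists were 1.40e-05 and 0.000796, and each had an adjusted p = 0.412 with an estimated correlation. Of 19 lymphoid priming genes 9 rose and 2 fell (median 0.47, within sets 0.30 and 0.64; camera adjusted p = 0.00266), with the cytokine receptor Flt3 at log2 0.62. Inflammatory NF-kB genes rose in 9 of 19 cases (median 0.54, within sets 0.37 and 1.09; camera adjusted p = 1.40e-05), including the chemokine Ccl3 (log2 1.56). Monocyte genes rose in 12 of 24 (median 0.52, camera adjusted p = 3.44e-06), mostly in the higher-numbered set (within sets 0.12 and 0.88). Each of these 3 lists had an adjusted p = 0.463 with an estimated correlation. Of 23 erythroid markers 13 fell, including the transcription factor Klf1 (log2 -0.71) and the ankyrin Ank1 (-0.88), and the rising pair was Hbb-bs (1.69) and Hbb-bt (1.47). That list had a median of -0.47 (within sets -0.40 and -0.68; camera adjusted p = 0.000117, adjusted p = 0.463 with an estimated correlation).

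Further lists passed in HSPC, all upward by median. These were neutrophil genes (6 of 27 rose, median 0.55, adjusted p = 4.27e-06), plasmacytoid dendritic cell markers (3 of 14, 0.34, adjusted p = 0.00443) and late B maturation genes (4 of 15, with Cd55 falling, 0.47, adjusted p = 0.00859). Each had an adjusted p = 0.463 with an estimated correlation. Neutrophil genes did not hold within sets, at -0.02 in the lower- and 1.02 in the higher-numbered set. B-cell lineage genes (8 of 22 rose and 2 fell, 0.35, adjusted p = 0.0387) had an adjusted p = 0.519 with an estimated correlation. Megakaryocyte markers (5 of 19, 0.31, adjusted p = 0.00287) and handling stress genes, the immediate early and heat shock genes that respond to cell isolation (7 of 19, 0.62, adjusted p = 0.00219), had an adjusted p = 0.465 with an estimated correlation. Stromal markers (4 of 8, 0.31, adjusted p = 0.0352) had an adjusted p = 0.463 with an estimated correlation. Interferon-stimulated genes (4 of 30, 0.28, adjusted p = 0.00859) had an adjusted p = 0.673 with an estimated correlation. Within the lower- and higher-numbered sets the medians were 0.11 and 0.63 for plasmacytoid dendritic cell, 0.26 and 0.65 for late B maturation, 0.18 and 0.57 for B-cell lineage, 0.10 and 0.39 for megakaryocyte, 0.34 and 0.76 for handling stress and 0.29 and 0.67 for stromal genes. Interferon-stimulated genes were higher mainly in the lower-numbered set, at 0.48 and 0.04. Without 1 library the B-cell lineage call was lost in 5 fits (without control 2 or 4 or Trsp KO 1, 3 or 4, adjusted p up to 0.0798), and over all alternatives in 10 of 23. The stromal call was lost without control 3 or 4 or Trsp KO 4 (up to 0.0921) and the interferon call without control 2 or Trsp KO 2 (up to 0.266). Lists that did not pass in HSPC were selenocysteine machinery (median -0.02, adjusted p = 0.475), ferroptosis (0.08, 0.920), cholesterol synthesis (0.02, 0.941), p53 targets (0.16, 0.300), ATF4 targets (0.15, 0.102), endoplasmic reticulum chaperones (0.13, 0.0622) and mitochondrially encoded genes (-0.06, 0.108). The same was true of NK (0.11, 0.852), T-cell (0.49, 0.113), plasma-cell (0.16, 0.143) and basophil markers (0.01, 0.941).

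Over all 13310 genes tested in HSPC, limma called 1709 higher and 1540 lower at a Benjamini-Hochberg threshold of 0.05, and 222 and 120 of these differed at least 2-fold. The groups did not overlap for 3551 genes, 26.7% of those tested, where chance gives 2.86%. The count varied with the library left out: it was 4688 without control 1, 2617 without control 2, 2128 without control 3 and 1966 without control 4. It was 2686 without Trsp KO 1, 2078 without Trsp KO 2, 1791 without Trsp KO 3 and 1590 without Trsp KO 4. These fits also had fewer libraries. Of the genes named above, Cd55 lost its call without 1 or another library (adjusted p reaching 0.0758).

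In prepro-B cells, 12 NRF2 targets rose, and 5 late B maturation genes, 6 NK markers and 6 plasmacytoid dendritic cell markers fell. Nqo1 rose from a normalised read count of 256 ± 30 (SD, n = 4) to 2184 ± 723 and Srxn1 from 105 ± 34 to 717 ± 82. Of 36 NRF2 targets 12 rose and 0 fell by limma (adjusted over the list alone, 27 and 0), with a median of log2 0.63 (within sets 0.47 and 0.73; camera adjusted p = 2.49e-31, adjusted p = 0.0095 with an estimated correlation). Of 18 late B maturation genes 5 fell, 4 of them in the class II antigen presentation pathway: Cd74 (log2 -1.24), H2-Aa (-1.31), H2-Ab1 (-1.21) and H2-Eb1 (-1.26). The list median was -0.71 (within sets -0.54 and -0.96; camera adjusted p = 2.33e-14, adjusted p = 0.00446 with an estimated correlation).

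Of 19 NK and innate lymphoid markers 6 fell, including the receptor Klra8 (log2 -2.90), Ncr1 (-1.59) and the granzyme Gzma (-1.81), with a median of -0.76 (within sets -0.76 and -0.92; camera adjusted p = 6.32e-16, adjusted p = 0.0356 with an estimated correlation). Of 18 plasmacytoid dendritic cell markers 6 fell, including Klk1 (-2.25) and Ly6d (-1.13), with a median of -0.76 (within sets -0.46 and -0.97; camera adjusted p = 1.03e-21, adjusted p = 0.0562 with an estimated correlation). B-cell lineage genes had a median of -0.57 (within sets -0.15 and -0.76; camera adjusted p = 2.82e-08, adjusted p = 0.0356 with an estimated correlation). Of the 34 tested, only Fcrla (-1.86) and the adaptor Blnk (-0.99) passed, and 12 fell and 2 rose adjusted over the list alone. Lymphoid priming genes had a median of -0.39 with 3 of 20 falling, mostly in the higher-numbered set (within sets -0.10 and -0.66; camera adjusted p = 6.82e-09, adjusted p = 0.123 with an estimated correlation). T-cell markers had a median of -0.41 with Cd4 falling (within sets -0.29 and -0.60; camera adjusted p = 0.000327, adjusted p = 0.355 with an estimated correlation).

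Among erythroid markers in prepro-B cells, the beta-globin genes rose most. Of 23 erythroid markers 6 rose, led by Hbb-bs (log2 3.29) and Hbb-bt (3.18), with a list median of 0.33 (within sets 0.16 and 0.56; camera adjusted p = 3.72e-10, adjusted p = 0.128 with an estimated correlation). The share of reads on the 4 adult globin genes was 0.0749% to 0.155% in control and 0.553% to 1.14% in Trsp KO libraries. Neutrophil genes had a median of 1.33, yet 0 of 30 passed singly by limma, and within sets the median was -0.59 and 3.05, so the pooled value did not hold (camera adjusted p = 9.84e-13, adjusted p = 0.268 with an estimated correlation). Mitosis genes had a median of 0.33 with 0 of 30 called and 11 called adjusted over the list alone (within sets 0.19 and 0.49; camera adjusted p = 4.19e-15, adjusted p = 0.123 with an estimated correlation). Glycolysis genes (median 0.21, adjusted p = 7.68e-06) and genes higher in aged stem cells (0.38, adjusted p = 2.87e-05), with Pkm and Aldh1a1 the single risers, each had an adjusted p = 0.0544 with an estimated correlation. Monocyte genes (0.31, adjusted p = 0.000646, 0.349 with an estimated correlation), ATF4 targets (0.32, adjusted p = 0.00725, 0.128), replication genes (0.11, adjusted p = 0.00471, 0.628), handling stress genes (0.20, adjusted p = 0.0481, 0.682) and interferon-stimulated genes (-0.21, adjusted p = 0.0377, 0.658) also passed with the preset correlation. Within sets the medians were 0.21 and 0.20 for glycolysis, 0.19 and 0.55 for aged stem cell, 0.17 and 0.35 for monocyte, 0.18 and 0.36 for ATF4 and 0.11 and 0.13 for replication genes. Of these calls, those of interferon-stimulated genes (without control 3 or 4 or Trsp KO 1, 3 or 4, adjusted p up to 0.543), handling stress genes (without control 3 or Trsp KO 1 or 2, up to 0.453), replication genes (without control 4 or Trsp KO 1, up to 0.21) and monocyte genes (without Trsp KO 4, 0.109) were lost. Handling stress and interferon-stimulated genes changed sign between sets, at -0.22 and 0.57, and at 0.11 and -0.57. The ATF4 call was lost with genes of mean at least 50.

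The largest single rises in prepro-B cells by the fixed rule were the heat shock genes Hspa1b (log2 3.75) and Hspa1a (3.54), Hbb-bs, Hbb-bt, Nqo1 (3.04), Srxn1 (2.80), Ttc12 (2.79) and Tinagl1 (2.78). The largest falls were Spon2 (log2 -3.04), Klra8, Trim2 (-2.68), Sepw1, Gpx1 (-2.40), the kallikrein Klk1b27 (-2.40), Klra4 (-2.31) and Klk1. Of 14091 genes tested, limma called 54 higher and 62 lower (36 and 44 of them at least 2-fold), and 1484 had an unadjusted p under 0.05. The groups did not overlap for 863 genes, 6.12% against a chance share of 2.86%. The calls of Hspa1b, Hspa1a, Ttc12, Spon2, Trim2, Klk1b27 and Blnk were lost without 1 or another single library, with adjusted p reaching 0.0849 for Spon2 and 0.327 for Ttc12 over the alternatives. The same held for Dio2 (reaching 0.418), Sephs2 (0.163), Pkm (0.205), Aldh1a1 (0.144) and Cd4 (0.238). The count was 56 without control 1, 69 without control 2, 54 without control 3 and 68 without control 4. It was 86 without Trsp KO 1, 108 without Trsp KO 2, 58 without Trsp KO 3 and 51 without Trsp KO 4. It was 34 without both Trsp KO 3 and 4, which stood highest in neutrophil genes. These fits also had fewer libraries. The number of higher genes fell from 54 to between 18 and 38 with 1 library left out (18 without Trsp KO 4, 33 without Trsp KO 2) and to 27 with a replicate block.

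In pre-B cells, 24 neutrophil and 8 basophil genes rose and 19 B-lineage genes fell, while the calls of these lists did not hold with an estimated correlation. Of 30 neutrophil and granule genes 24 rose, among them the granule protein gene Ngp (log2 4.72 ± 0.69, SE, n = 4) and the calgranulin S100a9 (4.57 ± 0.73). The list median was 3.09 (within sets 2.19 and 3.77; camera adjusted p = 6.98e-18, adjusted p = 0.16 with an estimated correlation). Of 15 basophil, mast cell and eosinophil markers 8 rose, including Ccl9 (3.42) and the histidine decarboxylase Hdc (3.34), with a median of 3.41 (within sets 3.60 and 2.42; camera adjusted p = 2.44e-07, adjusted p = 0.16 with an estimated correlation). Of 28 monocyte genes 12 rose, including the chemokine receptor Cx3cr1 (3.91) and Tyrobp (2.13), with a median of 2.29 (within sets 1.47 and 2.95; camera adjusted p = 7.42e-11, adjusted p = 0.291 with an estimated correlation). Of 36 B-cell lineage genes 19 fell and 0 rose by edgeR (adjusted over the list alone, 23 and 5), including Rhoh (-1.53), the coactivator Pou2af1 (-1.25), Cd72 (-1.37) and the antigen receptor subunit Cd79a (-1.14). That list had a median of -0.78 (within sets -0.74 and -0.90; camera adjusted p = 7.42e-11, adjusted p = 0.16 with an estimated correlation).

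Some NRF2 and ATF4 targets also rose in pre-B cells. Of 36 NRF2 targets 19 rose and 0 fell by edgeR (28 and 0 adjusted over the list alone), including the glutathione reductase Gsr (log2 3.51), Srxn1 (5.20) and Nqo1 (4.61), with a median of 1.08 (within sets 0.85 and 1.52; camera adjusted p = 7.5e-16, adjusted p = 0.16 with an estimated correlation). Of 23 ATF4 targets 8 rose, including the pseudokinase Trib3 (4.96) and the amino acid transporter Slc7a5 (1.37), with a median of 1.05 (within sets 0.69 and 1.27; camera adjusted p = 1.03e-06, adjusted p = 0.16 with an estimated correlation). Late B maturation genes had a median of -0.59 (within sets -1.05 and -0.51), and the interleukin receptor Il2ra (-2.27), the transcription factor Spib (-1.73) and S1pr1 (-0.90) fell (camera adjusted p = 1.64e-05, adjusted p = 0.506 with an estimated correlation). The lymphoid priming list did not pass (median -0.02, camera adjusted p = 0.082): of 20 genes 3 fell, among them Ly6d (-2.04) and Ikzf1 (-0.77), and 1 rose.

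Other lists that passed in pre-B cells were all higher by median. Genes higher in aged stem cells (6 of 19 rose, median 1.53, adjusted p = 9.40e-05) and long-term stem cell genes (2 of 19, 1.38, adjusted p = 0.00156) each had an adjusted p = 0.16 with an estimated correlation. NK markers (1 of 16, 1.39, adjusted p = 0.00156) and ferroptosis genes (3 of 22, with Acsl4 falling, 0.38, adjusted p = 0.00621) each had an adjusted p = 0.408 with an estimated correlation. Megakaryocyte markers (2 of 14, 0.97, adjusted p = 0.0409), glycolysis genes (5 of 18, 0.40, adjusted p = 1.64e-05) and cholesterol synthesis genes (1 of 24, 0.45, adjusted p = 0.000177) each had an adjusted p = 0.365 with an estimated correlation. T-cell markers (0 of 13 by edgeR, 1.18, adjusted p = 0.0409) and replication genes (2 of 30, 0.31, adjusted p = 0.000279) had an adjusted p = 0.618 with an estimated correlation, and mitosis genes (0 of 30 by edgeR, 0.29, adjusted p = 0.00141) had 0.67. The T-cell call rested on the lower-numbered set (within sets 1.88 and 0.06) and was lost in 11 of 22 alternatives, among them without control 1, 2 or 3 or Trsp KO 2 (adjusted p up to 0.465). The calls of ferroptosis (0.0736) and erythroid genes (0.164) were lost without Trsp KO 4, of mitosis genes without control 1 or Trsp KO 4 (up to 0.0855) and of megakaryocyte markers without control 2 or Trsp KO 2 or 3 (up to 0.113). Within sets the medians of the others were 1.11 and 2.35 for aged stem cell, 1.44 and 1.05 for long-term stem cell, 1.42 and 1.04 for NK, 0.21 and 0.66 for ferroptosis and 2.13 and 0.72 for megakaryocyte genes. They were 0.46 and 0.41 for glycolysis, 0.67 and 0.34 for cholesterol synthesis, 0.30 and 0.36 for replication and 0.20 and 0.36 for mitosis genes. Erythroid markers had a median of 1.75 with Nfe2 the single riser among 23 (camera adjusted p = 0.00374, adjusted p = 0.691 with an estimated correlation). They did not hold within sets, at -0.22 and 2.10, and globin reads took 0.777% to 1.201% of control libraries but 4.86%, 0.102%, 6.76% and 14.9% of Trsp KO libraries 1 to 4.

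The largest rises in pre-B cells by the fixed rule were in genes that control libraries barely held. Ms4a2, a chain of the IgE receptor, and Osgin1 had 0 reads over the 4 control libraries, and with a floor of 3 reads over the group they were at least 215.7-fold and at least 133.8-fold higher. Msr1, Mmp9, Alox5 and Ttc39c had 3, 3, 2 and 3 control reads, with ratios of 220.3 (95% counting interval 75.0 to 1071), 222.4 (75.8 to 1082), 241.0 (66.3 to 1996) and 145.5 (49.4 to 708.3). Single libraries carried much of some: normalised values were 284.8 in Trsp KO 2 and 52.5 to 58.8 in the others for Alox5, 429.6 in Trsp KO 2 and 8.28 to 89.4 in the others for Ms4a2, and 5.79 to 422.7 for Mmp9. Qpct and Pla2g7 rose by log2 5.86 and 5.81. The largest falls were Rgs16 (log2 -4.11), the eosinophil granule gene Prg3 (-3.49), Klra1 (-2.57), Mrvi1 (-2.47), Hspa2 (-2.43), Sepw1, Klc3 (-2.40) and Slco5a1 (-2.34). Of 13762 genes tested, edgeR's quasi-likelihood test called 599 higher and 504 lower (501 and 201 of them at least 2-fold), and 3462 had an unadjusted p under 0.05. The groups did not overlap for 2137 genes, 15.5% against a chance share of 2.86%.

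Single libraries moved the pre-B results. The calls of Ms4a2, Mmp9, Pla2g7, Rgs16, Mrvi1, Klc3, S1pr1, Acsl4 and Nfe2 were lost without 1 or another library, with adjusted p reaching 0.0519 for Ms4a2 and 0.196 for Pla2g7 over the alternatives. The count was 453 without control 1, 482 without control 2, 528 without control 3 and 1240 without control 4. It was 1013 without Trsp KO 1, 1546 without Trsp KO 2, 507 without Trsp KO 3 and 850 without Trsp KO 4. It was 277 without both Trsp KO 3 and 4, which stood highest in neutrophil and erythroid genes. These fits also had fewer libraries. Each called list of pre-B cells lost its call with an estimated correlation.

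**Figure D2:**
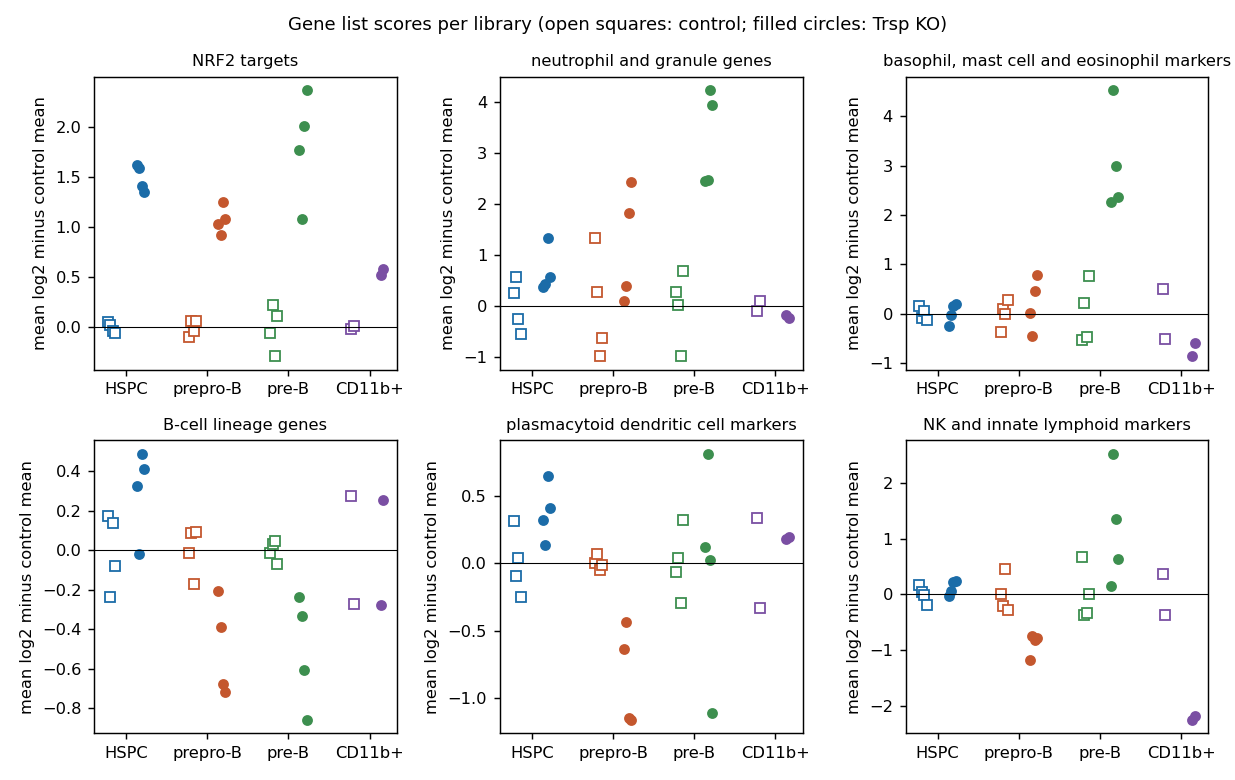
Scores of 6 gene lists per library (vertical axis, mean log2 value of the list minus the mean of the control libraries; open squares are control and filled circles Trsp KO) in 4 populations. The 4 Trsp KO pre-B libraries score 2.45 to 4.23 for neutrophil genes, above every control, whereas prepro-B scores of the same list overlap between genotypes.

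CD11b+ cells had the fewest called genes besides the selenoprotein genes, but with 2 libraries per genotype where the other populations had 4. Transcripts of the mitochondrial genome were higher: COX3 rose from a normalised read count of 29797 ± 2725 (SD, n = 2) to 50937 ± 3268, and ND4, COX1 and COX2 rose by log2 0.75, 0.67 and 0.65. Of the 13 mitochondrially encoded genes 4 rose and 0 fell by limma (adjusted over the list alone, 12 and 0), with a median of 0.65 (camera adjusted p = 1.58e-25, adjusted p = 0.359 with an estimated correlation). NRF2 targets had a median of 0.29 with 0 of 33 called and 8 called adjusted over the list alone (camera adjusted p = 6.24e-08, adjusted p = 0.303 with an estimated correlation). NK markers had a median of -2.22 (-0.47 with genes of mean at least 50, -0.90 without Trsp KO 2 and -2.92 without the filter) with 1 of 15 called, Gzma falling from 262 ± 64 to 10.1 ± 10.9, a log2 change of -5.00 (camera adjusted p = 2.66e-08, adjusted p = 0.303 with an estimated correlation). Mitosis (-0.38, adjusted p = 3.10e-14), replication (-0.21, adjusted p = 4.29e-05), neutrophil (-0.20, adjusted p = 6.24e-08) and basophil lists (-0.72, adjusted p = 4.29e-05) had lower medians with 0 members called by limma, and each had an adjusted p = 0.643 with an estimated correlation. The erythroid list (-0.55, adjusted p = 2.69e-07), also with 0 called, had an adjusted p = 0.303 with an estimated correlation. Its median ran from -0.69 to -0.21 over the alternatives. The basophil call was lost without control 1 (median -0.07, adjusted p = 0.626) and the replication call without control 2 (-0.11, adjusted p = 0.0531).

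The remaining called genes of CD11b+ cells by the fixed rule were Clcnka, Pir (log2 2.46) and Stfa1 (1.94), which rose, and the calcium uptake regulator Micu1 (-1.26), the metalloproteinase inhibitor Timp2 (-1.12) and Gpx4 (-0.98), which fell. Clcnka, a chloride channel gene, had 0 reads in both control libraries and was at least 115.5-fold higher with a floor of 3 reads over the group. Of 12853 genes tested, limma called 7 higher and 11 lower, and 850 had an unadjusted p under 0.05. The groups did not overlap for 4586 genes, 35.7% where chance gives 33.3%. Without control 1 the count was 5, without Trsp KO 1 it was 5 and without Trsp KO 2 it was 4. Only Gpx1 among these named genes kept its call in each fit that left out 1 library.

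Across populations, 4 genes changed in each: Sepw1, 2700094K13Rik and Sepp1 fell and Pir, an iron-binding nuclear protein gene (chromosome X, 164269431 to 164373013), rose. These were counted over the 11204 genes tested in all 4 tables. In HSPC, prepro-B and pre-B cells 35 genes changed, 34 of them the same way, including the catalase Cat, the glutathione synthesis gene Gclm, Gsr, Gsta3, Gstm1, Me1, Nqo1, Srxn1 and the lipoprotein lipase Lpl. Mctp2 was the exception. Rising genes shared by HSPC and prepro-B cells numbered 41 where 7.14 were expected by chance (one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 4.63e-25). HSPC and pre-B cells shared 247 rising genes where 73.6 were expected (exact adjusted p = 9.95e-76), while their 39 shared falling genes were no more than the 55.5 expected (exact adjusted p = 0.995). Prepro-B and pre-B cells shared 33 rising genes against 2.38 expected. Of 422 genes called in both HSPC and pre-B cells 136 changed in opposite directions, of 58 in HSPC and prepro-B cells 7 did, and of 47 in prepro-B and pre-B cells 0 did. Library numbers recur between prepro-B, pre-B and CD11b+ cells, with the same genotype at each number. Whether populations came from the same mice is not known, and the overlap tests treat them as independent. The tests also treat genes as independent, although genes of a pathway or cell type can move together, so their p-values may be too small. Granulocyte cells or RNA inside the pre-B gate, left open below, were not separated from the rises shared with pre-B cells.

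Globin transcripts changed in composition as well as amount. In HSPC the ratio of beta-globin reads (Hbb-bs and Hbb-bt, chromosome 7, 103812524 to 103827928) to alpha-globin reads (Hba-a1 and Hba-a2, chromosome 11) was 0.72 to 1.15 in controls and 2.46 to 4.34 in Trsp KO libraries. The log2 difference was 1.82 (within sets 2.05 and 1.59; two-sided exact permutation p = 0.0286, the smallest that 4 against 4 libraries can give). It was 0.94 in prepro-B and 0.39 in pre-B cells, each with the same exact permutation p, and 0.14 in CD11b+ cells, where the exact permutation p = 0.333 is the smallest possible. Reads shared between the near-identical globin copies were counted by the authors in a way not given in the sources used here, so the values of single globin genes are uncertain.

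**Figure D3:**
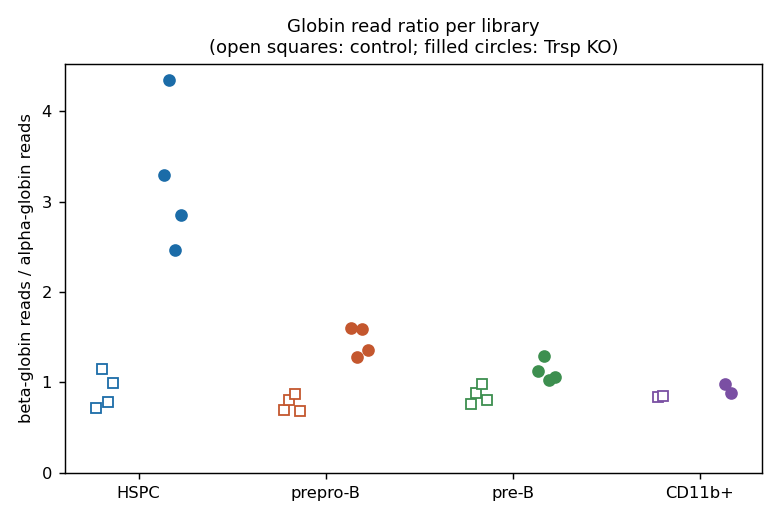
Ratio of beta-globin to alpha-globin reads per library (vertical axis, linear scale; open squares are control and filled circles Trsp KO) in 4 populations. In HSPC the controls lie between 0.72 and 1.15 and the Trsp KO libraries between 2.46 and 4.34, without overlap.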

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

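All tests of explanations for the patterns below were chosen after the results were seen, except the test of genes near the beta-globin locus and the counts over other splits of the samples. Of 396 groups of 4 libraries, 20 (5.05%) had a library standing apart, where chance gives 19.8.

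In pre-B cells of Trsp KO mice, the medians of the neutrophil, monocyte and basophil lists were above 0 and that of B-lineage genes below 0. Not all members passed singly, and each of these list calls was lost with an estimated correlation. A lower share of B cells alone could raise the markers of all other cell types alike. The neutrophil list rose by 2.29 (log2) more than the mean of the T-cell, NK, megakaryocyte and stromal lists (SD of the Trsp KO libraries 1.41, exact permutation p = 0.0286, the smallest possible). This cannot decide it, because the neutrophil list was chosen after its rise was seen and markers near 0 reads need not rise alike. The neutrophil median was 3.11 with globin genes left out before scaling and 3.09 with them. This cannot decide on a large share of globin reads, because leaving them out shifts all other genes of a library alike. Granulocyte cells or RNA inside the gate stay open. Taken from the neutrophil list, a 1.26% share of CD11b+-like RNA would raise 96 genes outside the lists at least 2-fold. Of these, 93 had a change above 0, with a median rise of log2 2.13 against a predicted 1.21. As higher, 29.2% (28) passed, between the 50% set for and the 10% set against it. In simulated pre-B data 36.2% of 2-fold and 73.5% of 4-fold changes were recovered, over genes of all levels. The genes of this test were mostly low in control libraries. The simulation therefore does not tell what pass share to expect, and the pass share cannot decide. A myeloid programme switched on within pre-B cells after Trsp loss was not tested and cannot be told apart from such cells.

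In HSPC of Trsp KO mice the beta-globin genes were higher and the alpha-globin genes were not. More erythroid cells would raise the other erythroid markers too. The mean of the 19 markers other than globins differed by -0.66 (Trsp KO minus control, log2, two-sided exact permutation p = 0.0286). This argues against more cells of the stages that these markers cover. The fall of the erythroid list was already known when this test was chosen. RNA of late erythroid cells, mostly globin, was not tested apart. A sequence variant that acted alike in every population would shift the ratio equally. The shift was 1.43 larger in HSPC than in pre-B cells (permutation p = 0.000816 over all 4900 arrangements). A variant acting differently by population was not tested. Whether the region around the locus changed cannot be told apart from the wide change of HSPC genes: 26.3% of 80 tested genes within 5 Mb on chromosome 7 changed, against 24.8% elsewhere (one-sided Fisher's exact p = 0.425). A change in globin regulation in progenitors is a hypothesis these data leave open.

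In prepro-B cells of Trsp KO mice, the medians of the NK and plasmacytoid dendritic cell lists were below 0. Most of their markers did not pass singly, and the plasmacytoid dendritic cell call was lost with an estimated correlation (camera adjusted p = 0.0562). Without Trsp KO 3 and 4, the libraries highest in neutrophil genes, the plasmacytoid dendritic cell median was -0.52, against -0.76 with them. The NK median was -0.91, against -0.76 with them. The larger limma camera adjusted p was 2.94e-13 with the preset correlation, and an estimated correlation was not run on that fit. Dilution by other RNA in those libraries alone is argued against. It may hold part of the plasmacytoid dendritic cell fall. A lower share of NK and plasmacytoid dendritic cells inside the gate and lower expression within them were not tested and stay open.

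Over the 35 splits of the 8 libraries of a population, the real split alone gave as many changed genes as were called. These were 3249 in HSPC (highest other 0), 116 in prepro-B (highest other 3) and 1103 in pre-B cells (highest other 3). Standing first of 35 is the most that these splits can show, so chance is not excluded. Results were not adjusted for the number compared. The real split was also alone in the size of the selenoprotein median in HSPC (0.495, highest other 0.337) and in prepro-B cells (0.489, highest other 0.370). In pre-B cells it was not alone, as 3 splits, the real one included, were as large (0.161, highest other 0.187). Nor was the real split alone in the number of lists that camera called with its preset correlation. With the real one included, 3 splits gave as many in HSPC (20, highest other 23), 3 in prepro-B (18, highest other 18) and 4 in pre-B cells (18, highest other 21). The other splits among these joined 3 libraries of a genotype with a library of the other, so they kept part of the genotype difference. Splits with 2 libraries of each genotype per group gave fewer lists than the real split. They gave 3 to 17 lists in HSPC, 2 to 14 in prepro-B and 4 to 15 in pre-B cells. Many lists were thus called with the preset correlation even where genotypes were evenly mixed. The split along library numbers gave 11, 8 and 15 lists.

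Libraries that stood apart from the other 3 of their group are given with the gap to the nearest library as a share of the group's range. In HSPC these were Trsp KO 2 for the handling stress score (0.952) and for Gpx1 (0.935), and Trsp KO 3 for Msrb1 (0.884). In prepro-B cells they were Trsp KO 2 for the interferon (0.835) and erythroid scores (0.904), control 1 for Hspa1b (0.876) and Hspa1a (0.881), control 4 for Ttc12 (0.836) and Selm (0.878), Trsp KO 4 for Klra8 (0.889) and control 2 for Selo (0.904). In pre-B cells they were control 3 for the aged stem cell score (0.926), control 1 for the lymphoid priming score (0.853) and Trsp KO 1 for the stromal score (0.954). Among pre-B genes they were control 1 for Mmp9 (1), control 4 for Ttc39c (1), Qpct (1) and Pla2g7 (1), where the other controls had 0 reads, Trsp KO 2 for Alox5 (0.973) and Trsp KO 4 for Pla2g7 (0.85).

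The effect on list scores differed between populations in permutation tests of genotype within each population (Benjamini-Hochberg adjusted). These permutations treat the populations as independent, although some may have come from the same mice. Granulocyte cells or RNA inside the pre-B gate, left open above, were not separated from the genotype effect in differences that involve pre-B cells. Values are the Trsp KO minus control change of the first population minus that of the second, in log2. HSPC minus prepro-B was 0.424 for NRF2 targets, -0.402 for replication, -0.593 for mitosis, 0.88 for lymphoid priming, 0.8 for B-cell lineage, 1.18 for late B maturation, 1.22 for plasmacytoid dendritic cell, 1 for NK and -1.22 for erythroid genes. HSPC minus pre-B was -0.743 for selenoproteins, -0.913 for ferroptosis, -0.636 for replication, -0.54 for mitosis, -0.82 for long-term stem cell and -1.29 for aged stem cell genes. In the same pair it was 0.582 for lymphoid priming, 0.811 for B-cell lineage, 1.27 for late B maturation, -2.59 for neutrophil, -1.5 for monocyte, -3.01 for basophil and -1.12 for megakaryocyte genes. Prepro-B minus pre-B was -0.618 for selenoproteins, -1.01 for ferroptosis, -0.569 for cholesterol synthesis, -0.38 for p53 targets, -0.984 for ATF4 targets, -1.22 for long-term stem cell and -1.31 for aged stem cell genes. It was -1.52 for monocyte, -2.04 for NK, -0.491 for plasma-cell, -2.84 for basophil and -1.51 for megakaryocyte genes.

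In a joint edgeR quasi-likelihood model with population-by-genotype terms (Benjamini-Hochberg, 11204 genes), the change differed for 10 genes between HSPC and prepro-B, 1881 between HSPC and pre-B and 30 between HSPC and CD11b+ cells. It differed for 1038 genes between prepro-B and pre-B, 19 between prepro-B and CD11b+ and 899 between pre-B and CD11b+ cells. The model shares 1 dispersion per gene over populations of unequal spread. It also treats all libraries as independent, although library numbers recur between populations and some may share mice. Nor does it separate other cells or RNA inside the pre-B gate from the genotype effect. Values below are differences of log2 changes in this model. Slc7a11 rose more in HSPC than in prepro-B (4.37), pre-B (3.86) and CD11b+ cells (6.08), and Osgin1 more in HSPC than in CD11b+ cells (4.46).

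HSPC minus pre-B was -4.99 for Osgin1, -1.16 for Gpx1, -3.78 for Gpx3, -0.877 for Gpx4, -0.822 for Txnrd1, -1.45 for Txnrd2, -0.458 for Sep15 and -1.73 for Selm. It was -10.6 for Ms4a2, -6.74 for Alox5, -5.88 for Ttc39c, -6.02 for Qpct, 2.45 for Hspa2, -1.82 for Timp2, -3.2 for Hba-a1 and -3.2 for Hba-a2. Prepro-B minus pre-B was -7.81 for Osgin1, -3.66 for Cbr3, -2.95 for Pir, -2.43 for Srxn1, -1.15 for Gpx1, -3.34 for Gpx3, -0.923 for Txnrd1, -1.63 for Selm and -1.44 for Sepn1. It was -10.7 for Ms4a2, -7.09 for Alox5, -5.84 for Ttc39c, -6.02 for Qpct, 1.81 for Hspa2 and -2.53 for Timp2. Pre-B minus CD11b+ was 2.22 for Slc7a11, 9.45 for Osgin1, 4.91 for Cbr3, 2.36 for Pir, 2.99 for Nqo1, 4.05 for Gpx3, 1.77 for Txnrd1, 3.8 for Hbb-bs, 3.75 for Hbb-bt and 3.6 for Tinagl1. It was 10.6 for Ms4a2, 7.86 for Alox5, 6.95 for Ttc39c, 5.93 for Qpct, -1.42 for Hspa2, -0.913 for COX3, -0.756 for COX1 and 3.24 for Timp2. Fitted differences of Ms4a2 and Osgin1 involve control groups with 0 reads and depend on the prior count.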

How the results depend on the processing

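The fits without Trsp KO 3 and 4, limma on pre-B counts and the fits without globin genes were chosen after seeing the data. The number of changed genes ranged from 1590 to 4688 in HSPC, 51 to 108 in prepro-B, 453 to 1546 in pre-B and 4 to 13 in CD11b+ cells when 1 library was left out. DESeq2 called 332 genes in prepro-B, 2018 in pre-B and 68 in CD11b+ cells, and edgeR called 8 in CD11b+ cells. Without the filter the CD11b+ count was 6, and without both Trsp KO 3 and 4 the counts were 34 in prepro-B and 277 in pre-B cells, with fewer libraries. The share of higher genes in CD11b+ cells was 53.8% with quantile normalization and 12.5% with edgeR, against 38.9%. The replicate block gave 2797 changed genes in HSPC, 89 in prepro-B, 934 in pre-B and 31 in CD11b+ cells. The correlations of same-numbered libraries, -0.08 to 0.15, did not show pairing. With so few libraries they cannot exclude it. HSPC replicates 2 and 3 and pre-B replicate 1 were best matched by their own number, while the others were not. The cause of the other differences was not tested.

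The selenoprotein median kept its sign and its side of the threshold in HSPC, prepro-B and CD11b+ cells under the alternatives run, before adjustment over the lists. After that adjustment, camera with an estimated correlation lost the call in HSPC (0.0743) and CD11b+ cells (0.303), and the rotation test fry lost it in CD11b+ cells (0.183). In pre-B cells it was -0.043 without Trsp KO 3 and 4, and the mixed rotation test of fry, which ignores direction, passed at a median of 0.161. The overlap of rising genes between prepro-B and CD11b+ cells was 0 with edgeR's calls. Lists reversed in single fits: in prepro-B cells mitochondrially encoded genes (0.0733 without control 4, -0.208 without control 3), handling stress genes (-0.0647 without control 4, 0.392 without control 1) and basophil markers (0.291 without Trsp KO 2, -0.129 without control 1), and in CD11b+ cells monocyte genes (-0.168 without control 2, 0.156 without control 1) and interferon-stimulated genes (0.514 without Trsp KO 1, -0.307 without Trsp KO 2). The cause was not tested. Over all pairs of a named gene and an alternative, the gene stayed on its side of the threshold, called or not, in 2979 pairs for HSPC, 3074 for prepro-B, 2491 for pre-B and 2056 for CD11b+ cells, and lost its call in 145, 130, 214 and 74. Lists lost their call in 46, 45, 51 and 25 pairs. For the pre-B counts, edgeR with DESeq2's size factors called 1090 genes, and quantile normalization, library weights and recovered reads were not run, nor was the robust variance for lists, which camera lacks. With 2 libraries per genotype, leaving 1 out of CD11b+ cells leaves a lone library that is assumed to vary like the other group. The effect of depth was not tested, and genes with a mean under 10 were not tested.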

Other observations

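Gm20658, a long non-coding RNA gene (chromosome 12, 116102782 to 116111713, GRCm38) singled out after its values were seen, rose more than any coding gene named for HSPC. Its normalised read count was 3.15 ± 2.38 (SD, n = 4) in control HSPC and 1134 ± 135 in Trsp KO HSPC, a log2 change of 8.38 (limma, Benjamini-Hochberg adjusted p = 1.71e-06). In prepro-B cells the change was 7.19 (4.06 ± 4.79 to 485 ± 277), and in pre-B cells it had 0 reads in each control library and a mean of 424 ± 284 in Trsp KO libraries. In CD11b+ cells the change of 1.62 did not pass (limma, Benjamini-Hochberg adjusted p = 0.124).

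Trim30c, a gene of the tripartite motif family on chromosome 7 chosen after its values were seen, took a share of reads that varied widely between libraries of the same genotype. It took 0.00105% to 0.995% of control and 0.0573% to 0.541% of Trsp KO prepro-B libraries, and 0.000899% to 1.203% of control and 0.0656% to 1.07% of Trsp KO pre-B libraries. In CD11b+ cells the shares were 0.294% and 0.0719% in control and 0.370% and 0.386% in Trsp KO libraries, which did not overlap. Its difference between genotypes did not pass in prepro-B (limma, Benjamini-Hochberg adjusted p = 0.85), pre-B (edgeR, 0.933) or CD11b+ cells (limma, 0.52). In HSPC the share was at most 0.000114%, with an exact 95% interval of 0.0000720% to 0.000170% for that library.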
